A study of Homo sapiens with 41 samples.

How the data were processed

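The authors deposited CPM values (counts per 1e6 reads assigned to genes) for both sequencing runs in 1 table of 27126 gene symbols. Per the submitters' processing notes, the tools used upstream were Trim Galore 0.6.7, FastQC, HISAT2 2.2.1, featureCounts 2.0.1 and edgeR on GRCh38. The notes do not say which tool made which step, nor in what order filtering and scaling were done. The table held 96.4% to 99.5% of each library's total in most groups and 89.96% to 91.9% in hESC_CTRL, so genes were removed after the scaling. Whole reads were recovered by dividing each column by its smallest step, within a tolerance of 0.05 read. Of 123 columns, 40 were tied to the sample groups by their names and used. The other 83 matched no sample in the labels and were not used. For BAP_70, 7 columns were found for 8 samples, and within a group the columns could not be tied to single samples. The column names divide the libraries of the TSC and BAP run into 2 sets, called p and q here, whose meaning the labels do not give. Symbols were matched to GENCODE release 29 for positions, and 24055 matched once.

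Each run was fitted once with limma 3.58.1 (limma-trend) on log2(CPM + 1) in R 4.3.3, with genes kept at 1 CPM or more in at least 6 libraries (TSC and BAP run) or 3 libraries (hESC run). A gene passed where its adjusted p (Benjamini-Hochberg, within a comparison) was under 0.05 and its log2 fold change was at least 1 in size. The 9 comparisons of groups and the difference between models were listed before the data were examined. The p-values measure the spread between libraries, which may be technical, since nothing in the labels says that replicates were separate cultures. The SE values come from the same fits. Ranges for values of 0 cover counting error only.

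A set of 23 gene lists with 416 genes was fixed at the same time, and each list was tested with camera at a preset correlation of 0.01 between genes. The test was repeated with the correlation estimated from the data, and p-values were adjusted over the lists of a comparison. Counts of genes that passed are also given after adjustment over the genes of 1 list alone.

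Genes are named by a fixed rule. Genes chosen in advance as anchors are named whatever their result, and those too low to be tested, such as POU5F1 in the BAP groups, are given as levels. From each list that is described, up to 4 genes that passed with the largest fold change and at least 5 CPM in the higher group are named, or up to 2 of the highest genes if none passed. The 5 largest rises and the 5 largest falls among genes with at least 10 CPM and no overlap between groups complete the set. Genes known only by clone names and sex-linked marker genes were left out of the last step.

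Steps taken to stand for syncytiotrophoblast formation were compared between models with an interaction term. The fold changes over all tested genes were also correlated, with a jackknife over libraries. Profile similarity was Spearman correlation of each library with the mean log2 profile of each TSC group, and the differences were tested with an exact sign-flip test over the libraries of a group.

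The pipeline was tested on simulated data with known changes. Both simulated groups were drawn from 1 real group, which was TSC_CTB, BAP_40 or hESC_BAPD3, with about as many genes raised as lowered. Column sets and shifts in the share of reads left for other genes were not simulated. Libraries of hESC_BAPD3 were also closer to each other than those of hESC_CTRL. The rates below may therefore not hold for the real comparisons. At 6 libraries per group it recovered 47% of changes of 2-fold, 100.0% of 4-fold and 100.0% of 8-fold, and called 1 gene without a change among 12050 genes. At 7 and 6 libraries it recovered 31.3%, 98.5% and 98.5% of these changes and called 5 unchanged genes among 12611, and at 3 and 3 libraries 44.8%, 98.5% and 100.0% with 10 among 12914. A list raised in the simulation had a camera p of 1.57e-107, 3.83e-100 and 5.37e-87 in these designs, and a list left unchanged had 0.914, 0.72 and 0.408.

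Every comparison was rerun with other choices. These were pseudocounts of 0.25 and 5 CPM, no filter and a filter of 5 CPM, rescaling by median of ratios, by TMM and by quantiles, a fit on the compared groups alone, no fold threshold, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered whole reads, and leaving out each library in turn. DESeq2 gave no adjusted p for 2 genes per comparison in the TSC and BAP run and 11 in the hESC run. The libraries lettered A, B and C were also taken as blocks in the hESC run.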

Results

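RNA was sequenced from cultured human trophoblast and from human embryonic stem cells (hESC) in 41 samples, and 40 libraries of the deposited table could be tied to the sample groups. In the first of 2 sequencing runs, trophoblast stem cells (TSC) of the lines CT27 and CT-29 were collected as cytotrophoblast (TSC_CTB, n = 6). The treatment label reads undifferentiated for 5 of these samples and differentiated for 1, which could not be tied to a column and is included in all TSC_CTB values. TSC were also differentiated for 6 days with forskolin to syncytiotrophoblast (TSC_STB, n = 6), or with A83-01, NRG1 and Matrigel to extravillous trophoblast (TSC_EVT, n = 6). The same run held cells made from hESC by the BAP protocol and separated by size, under 40 µm (BAP_40, n = 6) and over 70 µm (BAP_70, n = 7 of 8 samples). BAP is known in the field as BMP4 with inhibitors of activin and FGF signalling, which the labels do not list. In the other run, hESC libraries were made from controls (hESC_CTRL) and at day 3 (hESC_BAPD3) and day 7 (hESC_BAPD7) of BAP, with n = 3 each. Assigned reads per library, in units of 1e6 reads, ranged from 33.3 (BAP_70) to 45.0 (TSC_CTB) in the first run. They ranged from 12.7 to 16.0 in hESC_CTRL, 8.57 to 8.74 in hESC_BAPD3 and 21.3 to 22.4 in hESC_BAPD7.

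Values are counts per 1e6 assigned reads (CPM), given as mean ± SD over the libraries of a group, and log2 fold changes (log2 FC) are on the log2(CPM + 1) scale. A gene without a read in any library of a group is listed at 0. Such genes, like those with 3 reads or fewer per library, are given as levels without a fold. The 3 reads that a value of 0 allows, for counting error only, were 0.188 to 0.237 CPM in hESC_CTRL, 0.343 to 0.350 CPM in hESC_BAPD3 and 0.134 to 0.141 CPM in hESC_BAPD7, and 0.0666 to 0.0900 CPM in the first run. Every value was a whole number of reads within a tolerance of 0.05. In hESC_BAPD7, 1611 genes stood at exactly 1 read in all 3 libraries, where counting noise allows at most 1090. The totals therefore equal sequenced reads only if counts were not altered before the table was made, and levels from the 2 runs may not be comparable. CGA took 12.9% ± 2.89 of the reads in TSC_STB, 6.93% ± 1.20 in BAP_70 and 37.3% ± 2.64 in hESC_BAPD7, so the share left for other genes differed between groups. Gene lists were tested with camera, and the lists described under each comparison were picked after their results were seen.

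Syncytiotrophoblast is the fused, hormone-producing layer of the placenta, and the comparison of TSC_STB with TSC_CTB (n = 6 and 6) asked which genes changed as it formed from stem cells. The 6 TSC_CTB libraries include the sample labelled differentiated. CGA (chromosome 6, 87085498 to 87095406), the gene of the alpha subunit of chorionic gonadotropin, rose from 5660 ± 4851 to 129020 ± 28916 CPM (log2 FC 4.92, SE 0.40, adjusted p = 3.44e-12). CGB5 (chromosome 19, 49043884 to 49045311), a gene of its beta subunit, rose from 534 ± 424 to 15298 ± 4483 CPM (log2 FC 5.18, SE 0.37, adjusted p = 3.09e-13). The pregnancy-specific glycoprotein gene PSG3 rose from 28.0 ± 16.4 to 2040 ± 625 CPM (log2 FC 6.33). The imprinted gene PEG10 fell from 682 ± 186 to 9.95 ± 2.88 CPM (log2 FC -5.95).

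Among 26 tested genes for STB hormones and secreted proteins, 22 rose, 0 fell and 4 did not pass (22 and 0 adjusted over the list alone; adjusted p = 6.29e-20, or adjusted p = 0.00991 with an estimated correlation). The inhibin subunit gene INHA rose from 10.6 ± 11.6 to 611 ± 217 CPM (log2 FC 6.15). ADAM12 rose from 2.00 ± 1.17 to 179.7 ± 66.2 CPM (log2 FC 5.92), with log2 FC of 5.70 for INSL4 and 5.39 for CGB7. Of 9 pregnancy-specific glycoprotein genes, all 9 rose (9 and 0 adjusted over the list alone; adjusted p = 1.01e-12, or adjusted p = 0.00991 with an estimated correlation). Besides PSG3 (chromosome 19, 42721638 to 42740569), the log2 FC were 5.86 for PSG6, 5.58 for PSG4 and 5.11 for PSG5. Both steroid enzyme genes named in advance rose. HSD3B1, whose product makes progesterone, rose from 409.5 ± 65.7 to 1179 ± 212 CPM (log2 FC 1.52), and the aromatase gene CYP19A1 from 617 ± 453 to 2198 ± 677 CPM (log2 FC 2.10).

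Of 18 genes for fusion and STB regulators, 8 rose, 2 fell and 8 did not pass (8 and 2 adjusted over the list alone; adjusted p = 0.000486, or adjusted p = 0.158 with an estimated correlation). ERVW-1, which encodes the fusogen syncytin-1, rose from 246 ± 112 to 941 ± 242 CPM (log2 FC 2.01). ERVFRD-1, which encodes syncytin-2, rose from 29.2 ± 22.6 to 65.8 ± 22.2 CPM (log2 FC 1.38). Its receptor gene MFSD2A rose from 10.2 ± 2.09 to 60.5 ± 19.2 CPM (log2 FC 2.41). SDC1 rose from 208 ± 132 to 1351 ± 423 CPM (log2 FC 2.86) and ERVV-1 from 42.7 ± 30.7 to 258 ± 59.6 CPM (log2 FC 2.84). The endogenous retroviral envelope gene ERVMER34-1 fell from 303 ± 46.1 to 41.3 ± 13.8 CPM (log2 FC -2.88). GCM1, a transcription factor gene of fusion, did not pass (72.0 ± 24.4 to 103 ± 11.9 CPM, log2 FC 0.59, adjusted p = 0.00638), but passed after median-of-ratios rescaling (1.13). Of 23 genes of interferon response and restriction, 16 rose, 0 fell and 7 did not pass (16 and 0 adjusted over the list alone; adjusted p = 3.60e-12, or adjusted p = 0.0128 with an estimated correlation). IFI27 (chromosome 14, 94104836 to 94116698) rose from 3.51 ± 2.85 to 302 ± 214 CPM (log2 FC 6.00). IFIT1 rose from 4.60 ± 2.32 to 111 ± 67.3 CPM (log2 FC 4.11), with log2 FC of 3.09 for MX1 and 2.92 for OAS2.

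Of 20 CTB and trophoblast stem cell markers, 1 rose, 11 fell and 8 did not pass (1 and 11 adjusted over the list alone; adjusted p = 0.073, or adjusted p = 0.471 with an estimated correlation), and the list as a whole did not pass, but did after median-of-ratios rescaling (adjusted p = 0.0275). LRP2 fell from 261 ± 58.6 to 19.7 ± 9.61 CPM (log2 FC -3.77), and TEAD4 from 66.7 ± 10.2 to 9.25 ± 2.98 CPM (log2 FC -2.76). PAGE4 fell by 3.29 on the log2 scale. TP63 (chromosome 3, 189631416 to 189897279), a transcription factor gene of the stem state, fell from 12.5 ± 2.77 to 4.43 ± 2.29 CPM (log2 FC -1.40). It did not pass after median-of-ratios rescaling (-0.94) or in edgeR (-0.97). The integrin gene ITGA6 did not pass (82.6 ± 13.5 to 43.0 ± 11.5 CPM, log2 FC -0.95, adjusted p = 0.00027). It passed without TSC_CTB replicate p3 (-1.02), TSC_STB replicate q3 (-1.04) or TSC_STB replicate p3 (-1.03). Of 26 proliferation genes, 0 rose, 16 fell and 10 did not pass (0 and 16 adjusted over the list alone; adjusted p = 0.0059, or adjusted p = 0.495 with an estimated correlation), and 11 fell after median-of-ratios rescaling. The log2 FC were -2.17 for MCM2, -1.99 for TOP2A, -1.98 for PLK1 and -1.96 for BUB1B. MKI67 did not pass (99.7 ± 24.3 to 57.4 ± 28.6 CPM, log2 FC -0.87, adjusted p = 0.0123). It passed in 4 of 27 alternatives, among them without TSC_CTB replicate q2 (-1.01) or TSC_STB replicate p3 (-1.08). Among the largest falls, the gastrin receptor gene CCKBR fell from 695 ± 154 to 21.4 ± 7.28 CPM (log2 FC -4.99). The RNA-binding protein gene LIN28A fell from 242 ± 34.7 to 11.1 ± 7.36 CPM (log2 FC -4.53), with log2 FC of -4.58 for FABP7 and -4.52 for ANPEP. HLA-G did not pass (127 ± 144 to 78.7 ± 85.2 CPM, log2 FC -0.74, adjusted p = 0.627).

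In limma, 4287 of 13618 genes passed the threshold, 941 higher and 3346 lower in TSC_STB. The median log2 FC of all genes was -0.44. After median-of-ratios rescaling it was -0.01, and 1664 genes were higher and 1394 lower, so the direction of the majority depended on the scaling. The share of mitochondrial reads was 1.96% ± 0.856 in TSC_STB (1.10% to 3.41%) and 0.666% ± 0.114 in TSC_CTB (0.496% to 0.803%), without overlap.

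**Figure D1:**
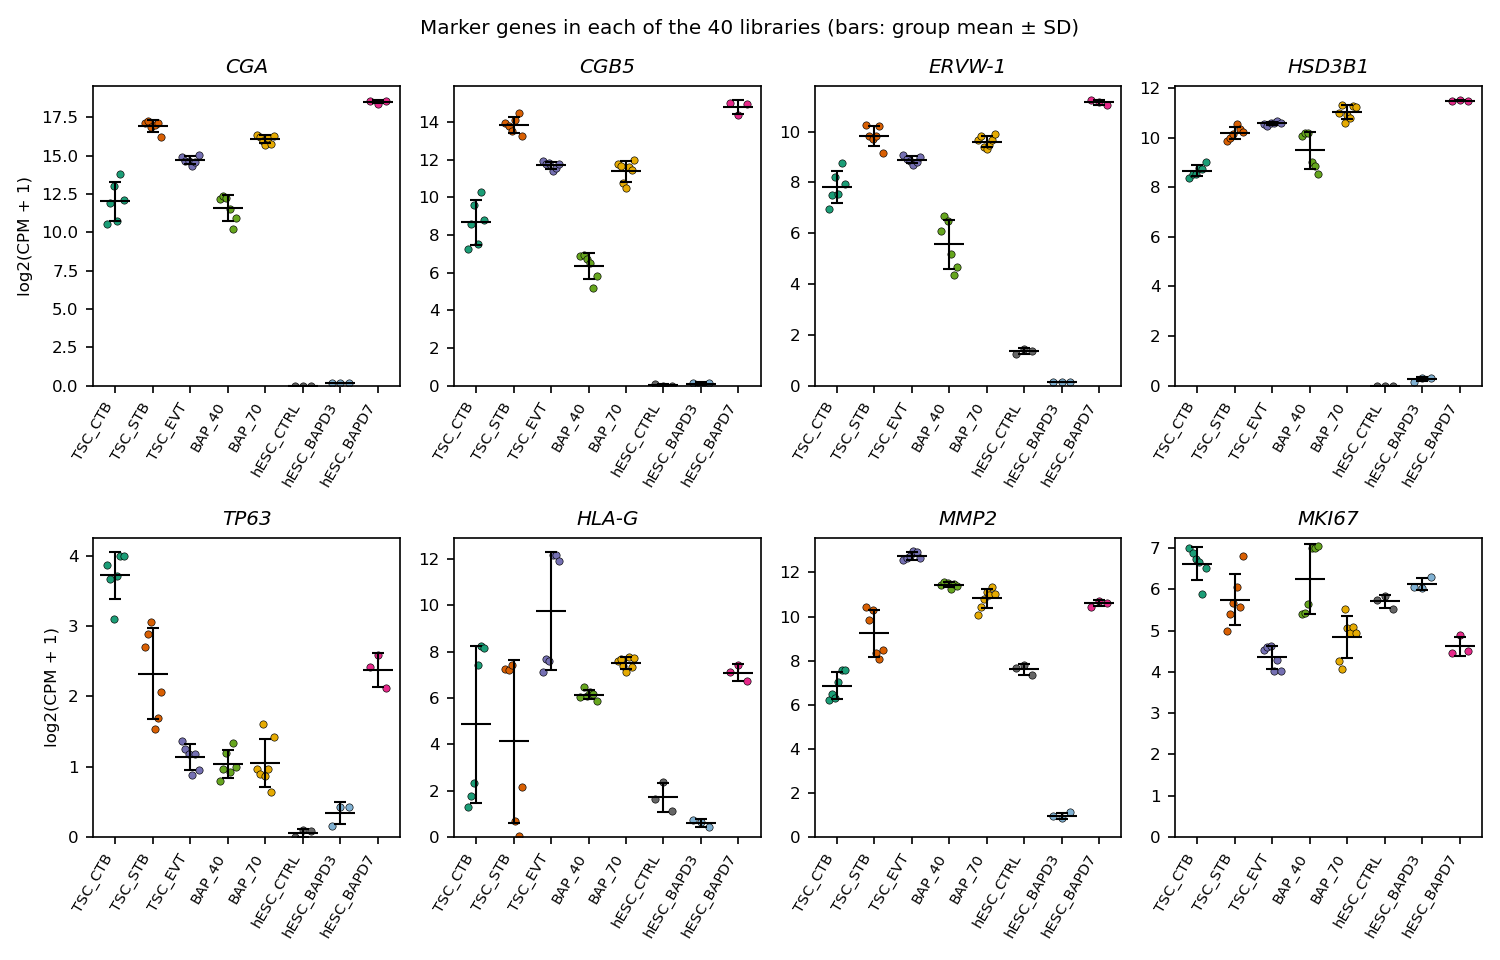
Log2(CPM + 1) of marker genes in each library of the 8 groups, with points for libraries and bars for group means ± SD. CGA reached 129020 CPM in TSC_STB, 69285 CPM in BAP_70 and 373310 CPM in hESC_BAPD7.

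Extravillous trophoblast invades the uterine wall, and the comparison of TSC_EVT with TSC_CTB (n = 6 and 6) asked which genes changed on that path, again with the TSC_CTB sample labelled differentiated included. The placental lactogen gene CSH1 (chromosome 17, 63894909 to 63896661) rose from 0.186 ± 0.138 to 3067 ± 521 CPM (log2 FC 11.33). The serine protease gene HTRA4 rose from 15.5 ± 13.0 to 3617 ± 155 CPM (log2 FC 8.19, SE 0.42, adjusted p = 1.20e-16). MMP2, which encodes a matrix-degrading protease, rose from 125 ± 54.7 to 6946 ± 848 CPM (log2 FC 5.89, SE 0.32, adjusted p = 3.18e-16). HLA-G (chromosome 6, 29826967 to 29831125), the class I gene typical of this lineage, rose from 127 ± 144 to 2267 ± 2305 CPM (log2 FC 4.90, adjusted p = 0.0014). Its 6 TSC_EVT libraries formed 2 sets that the column names tell apart, at 177 ± 35.9 CPM in set p and 4357 ± 426 CPM in set q (n = 3 each). The same sets were at 2.62 ± 1.28 and 252 ± 71.4 CPM in TSC_CTB.

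Of 23 EVT markers, 22 rose, 0 fell and 1 did not pass (22 and 0 adjusted over the list alone; adjusted p = 2.03e-20, or adjusted p = 0.000163 with an estimated correlation). The deiodinase gene DIO2 rose from 2.43 ± 1.26 to 839.8 ± 163 CPM (log2 FC 7.9998). FLT4 rose from 3.15 ± 1.58 to 555 ± 77.9 CPM (log2 FC 7.14), with a log2 FC of 6.23 for EBI3. The WNT inhibitor gene NOTUM rose from 39.8 ± 11.1 to 2661 ± 462 CPM (log2 FC 6.06). The transcription factor gene ASCL2 rose from 86.6 ± 10.6 to 1472 ± 281 CPM (log2 FC 4.06). The integrin gene ITGA1 rose from 26.7 ± 20.1 to 844 ± 274 CPM (log2 FC 5.21) and ITGA5 from 331 ± 39.3 to 3364 ± 438 CPM (log2 FC 3.34). The fibronectin gene FN1 rose from 186 ± 56.1 to 1335 ± 152 CPM (log2 FC 2.90). The laminin gene LAMA4 rose from 0.0692 ± 0.0811 to 611 ± 52.8 CPM. Of 26 STB hormone and secreted protein genes, 20 rose, 0 fell and 6 did not pass (20 and 0 adjusted over the list alone; adjusted p = 1.74e-12, or adjusted p = 0.053 with an estimated correlation). Besides CSH1, the log2 FC were 10.27 for CSH2, 8.70 for ADAM12 and 3.5016 for LEP. CGA rose from 5660 ± 4851 to 26902 ± 4975 CPM (log2 FC 2.67). Of 9 pregnancy-specific glycoprotein genes, all 9 rose (9 and 0 adjusted over the list alone; adjusted p = 8.14e-10, or adjusted p = 0.0348 with an estimated correlation), with log2 FC of 5.28 for PSG3, 5.08 for PSG6, 4.96 for PSG2 and 4.96 for PSG9.

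Of 20 CTB and trophoblast stem cell markers, 0 rose, 15 fell and 5 did not pass (0 and 15 adjusted over the list alone; adjusted p = 4.66e-05, or adjusted p = 0.257 with an estimated correlation). LRP2 fell from 261 ± 58.6 to 4.73 ± 3.43 CPM (log2 FC -5.73), and PEG10 from 682 ± 186 to 13.2 ± 1.60 CPM (log2 FC -5.54). The adhesion gene EPCAM fell from 350.4 ± 39.3 to 28.9 ± 14.9 CPM (log2 FC -3.71), with a log2 FC of -3.51 for TEAD4. TP63 fell from 12.5 ± 2.77 to 1.22 ± 0.274 CPM (log2 FC -2.59). ITGA6 did not pass (82.6 ± 13.5 to 44.2 ± 13.1 CPM, log2 FC -0.92, adjusted p = 0.000432). It passed in 3 of 27 alternatives, among them without TSC_EVT replicate p2 (-1.02), and ranged from -1.371 to -0.4756 over all of them. Of 26 proliferation genes, 0 rose, 23 fell and 3 did not pass (0 and 23 adjusted over the list alone; adjusted p = 4.07e-07, or adjusted p = 0.339 with an estimated correlation). MKI67 fell from 99.7 ± 24.3 to 19.7 ± 3.91 CPM (log2 FC -2.26), with log2 FC of -3.60 for PLK1, -3.37 for BUB1B, -3.34 for TOP2A and -3.31 for CDC20. Among the largest falls, LIN28A fell from 242 ± 34.7 to 1.83 ± 1.35 CPM (log2 FC -6.56). The fatty acid binding protein gene FABP5 fell from 511 ± 56.7 to 5.78 ± 1.63 CPM (log2 FC -6.26), with log2 FC of -5.84 for CCKBR and -5.79 for HAPLN1. In limma, 3624 genes passed, 1141 higher and 2483 lower in TSC_EVT, with a median log2 FC over all genes of -0.26. After median-of-ratios rescaling 1696 were higher and 1650 lower. The mitochondrial share was 0.997% ± 0.0834 in TSC_EVT, against 0.666% ± 0.114 in TSC_CTB.

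The comparison of TSC_EVT with TSC_STB (n = 6 and 6) set both differentiated states against each other, and levels are given for TSC_EVT against TSC_STB. NOTUM was at 2661 ± 462 against 4.95 ± 2.59 CPM (log2 FC 8.91), and ASCL2 at 1472 ± 281 against 16.2 ± 8.47 CPM (log2 FC 6.56). CSH1 was also higher in TSC_EVT, at 3067 ± 521 against 2.40 ± 1.24 CPM (log2 FC 9.88). The gonadotropin genes CGA and CGB5 were lower, CGA at 26902 ± 4975 against 129020 ± 28916 CPM (log2 FC -2.25) and CGB5 at 3367 ± 424 against 15298 ± 4483 CPM (log2 FC -2.14). CGA did not pass after quantile normalisation (log2 FC 0, adjusted p = 1), which gives the highest gene of every library the same value, and CGA was the highest in all 12. The stress-response cytokine gene GDF15 was at 204 ± 21.1 against 2667 ± 891 CPM (log2 FC -3.64).

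Of 23 EVT markers, 20 were higher, 0 lower and 3 did not pass (20 and 0 adjusted over the list alone; adjusted p = 2.06e-09, or adjusted p = 0.0192 with an estimated correlation). FLT4 was at 555 ± 77.9 against 6.46 ± 4.00 CPM (log2 FC 6.41) and MMP2 at 6946 ± 848 against 749 ± 500.1 CPM (log2 FC 3.51). HLA-G was at 2267 ± 2305 against 78.7 ± 85.2 CPM (log2 FC 5.64). Of 26 STB hormone and secreted protein genes, 4 were higher, 14 lower and 8 did not pass (4 and 14 adjusted over the list alone; adjusted p = 0.0129, or adjusted p = 0.477 with an estimated correlation), and the list did not pass after median-of-ratios rescaling (adjusted p = 0.107). CSH2 was higher (log2 FC 7.32) and INHA lower (-3.08). Of 20 placental transport genes, 0 were higher, 7 lower and 13 did not pass (0 and 7 adjusted over the list alone; adjusted p = 0.000678, or adjusted p = 0.369 with an estimated correlation). FABP5 was at 5.78 ± 1.63 against 56.9 ± 27.8 CPM (log2 FC -2.98) and the calcium-binding protein gene S100P at 381 ± 51.9 against 1006 ± 272 CPM (log2 FC -1.36). The log2 FC were -1.45 for SLC22A11, -1.18 for SLC3A2 and -1.18 for SDC1. These last 3 did not pass in the columns of set p alone (-0.78, -0.67 and -0.69). HSD3B1 was at 1526 ± 59.1 against 1179 ± 212 CPM (log2 FC 0.39, adjusted p = 0.12) and did not pass. Among the largest differences, PDE6H was at 719.9 ± 26.8 against 0.218 ± 0.322 CPM (log2 FC 9.25), with log2 FC of 8.79 for LAMA4 and 7.41 for SCUBE1. GLRX was at 16.2 ± 2.39 against 305 ± 85.2 CPM (log2 FC -4.11), with log2 FC of -4.41 for SIGLEC6, -4.28 for HMGCS2 and -4.24 for ODAPH. BIRC7, a gene of an inhibitor of apoptosis, was lower at 0.0186 ± 0.0297 against 28.0 ± 9.72 CPM. In limma, 2388 genes passed, 1482 higher and 906 lower in TSC_EVT, with a median of 0.12. After median-of-ratios rescaling 1052 were higher and 1305 lower. The mitochondrial share was 0.997% ± 0.0834 in TSC_EVT and 1.96% ± 0.856 in TSC_STB.

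BAP-treated hESC form small mononuclear cells and large syncytial sheets, and the comparison of BAP_70 with BAP_40 (n = 7 and 6) asked which genes marked the large fraction. CGA rose from 3459 ± 1705 to 69285 ± 11984 CPM (log2 FC 4.49, SE 0.38, adjusted p = 6.45e-11). CGB5 rose from 87.9 ± 35.0 to 2835 ± 953 CPM (log2 FC 5.03, SE 0.36, adjusted p = 1.70e-12). CYP11A1, the gene of the first enzyme of steroid synthesis, rose from 145 ± 59.3 to 1896 ± 258 CPM (log2 FC 3.80). ERVW-1 rose from 55.6 ± 34.0 to 788 ± 126 CPM (log2 FC 4.04), and GCM1 from 5.44 ± 1.61 to 36.2 ± 6.36 CPM (log2 FC 2.55). The proliferation marker gene MKI67 fell from 86.4 ± 46.6 to 29.1 ± 9.87 CPM (log2 FC -1.42).

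Of 26 STB hormone and secreted protein genes, 20 rose, 1 fell and 5 did not pass (20 and 1 adjusted over the list alone; adjusted p = 9.43e-22, or adjusted p = 0.00893 with an estimated correlation), led by log2 FC of 5.43 for CGB3, 4.93 for CGB8 and 4.54 for CGB7. Of 18 fusion and STB regulators, 11 rose, 0 fell and 7 did not pass (11 and 0 adjusted over the list alone; adjusted p = 2.62e-09, or adjusted p = 0.0218 with an estimated correlation). ERVFRD-1 rose from 8.84 ± 5.50 to 78.2 ± 30.0 CPM (log2 FC 3.14), and SDC1 from 214 ± 80.6 to 2191 ± 990.0 CPM (log2 FC 3.33), with a log2 FC of 2.68 for ERVV-1. Of 10 steroid synthesis genes, 6 rose, 0 fell and 4 did not pass (6 and 0 adjusted over the list alone; adjusted p = 2.62e-09, or adjusted p = 0.00893 with an estimated correlation). CYP19A1 rose from 109.6 ± 72.0 to 1179 ± 230.0 CPM (log2 FC 3.70), and the ferredoxin gene FDX1 from 122 ± 24.1 to 874 ± 216 CPM (log2 FC 2.82). HSD11B2, which encodes the enzyme that inactivates cortisol, rose from 7.85 ± 4.43 to 74.3 ± 29.3 CPM (log2 FC 3.19). HSD3B1 rose from 797 ± 381 to 2113 ± 403 CPM (log2 FC 1.54). Of 20 placental transport genes, 11 rose, 0 fell and 9 did not pass (11 and 0 adjusted over the list alone; adjusted p = 4.22e-08, or adjusted p = 0.0682 with an estimated correlation). S100P rose from 57.4 ± 24.1 to 907 ± 383 CPM (log2 FC 3.99). The sulfate transporter gene SLC13A4 rose from 17.5 ± 5.59 to 109 ± 12.4 CPM (log2 FC 2.63), with log2 FC of 2.64 for SLC22A11 and 1.93 for TFRC. Of 9 pregnancy-specific glycoprotein genes, 3 rose, 0 fell and 6 did not pass (3 and 0 adjusted over the list alone; adjusted p = 0.0419, or adjusted p = 0.479 with an estimated correlation), and the list did not pass after median-of-ratios rescaling (adjusted p = 0.237). PSG4 rose from 39.4 ± 33.1 to 107 ± 67.4 CPM (log2 FC 1.68), with log2 FC of 1.94 for PSG5 and 1.85 for PSG9. PSG5 did not pass in the columns of set q alone (0.57).

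Of 26 proliferation genes, 0 rose, 14 fell and 12 did not pass (0 and 14 adjusted over the list alone; adjusted p = 0.000226, or adjusted p = 0.489 with an estimated correlation), but 4 fell after median-of-ratios rescaling and 2 after TMM rescaling. TOP2A fell from 98.1 ± 34.1 to 33.5 ± 13.1 CPM (log2 FC -1.54). BUB1 (-1.29) and CENPF (-1.31) fell and did not pass after TMM rescaling (-0.99 and -0.997), nor CENPF in set q alone (-0.81). Among the largest falls, the lamin gene LMNB1 fell from 27.7 ± 11.7 to 6.68 ± 2.88 CPM (log2 FC -1.92). The immediate early gene FOS fell from 288 ± 110.0 to 89.2 ± 37.2 CPM (log2 FC -1.73), with log2 FC of -1.67 for BRIP1, -1.61 for STIL and -1.60 for APAF1. The imprinted gene PHLDA2 rose from 3.25 ± 7.94 to 191 ± 164 CPM (log2 FC 6.50), with 1 BAP_40 library far above the others. The keratin gene KRT23 rose from 0 to 60.5 ± 70.4 CPM. HLA-G did not pass (70.5 ± 10.4 to 184 ± 30.3 CPM, log2 FC 1.37, adjusted p = 0.352). Its libraries did not overlap, at 57.21 to 87.06 CPM in BAP_40 and 138.6 to 216 CPM in BAP_70. The p-value rests on a spread shared by all groups of the run, and HLA-G differed widely between the column sets of the TSC groups. HLA-G passed in a fit on the compared groups alone (1.37), with the column sets as a block (2.12), in set p alone (1.36) and in set q alone (1.45). TP63 did not pass (1.07 ± 0.290 to 1.13 ± 0.533 CPM, log2 FC 0.02, adjusted p = 0.948), and neither did VIM, the mesenchymal filament gene, by log2 FC (-0.49, adjusted p = 4.84e-06). The pluripotency factor gene POU5F1 was too low to be tested, at 0.00690 ± 0.0182 CPM in BAP_70 and 0.00945 ± 0.0146 CPM in BAP_40.

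In limma, 1419 genes passed, 778 higher and 641 lower in BAP_70, with a median of -0.32. After median-of-ratios rescaling 992 were higher and 114 lower. The share of mitochondrial reads was 3.59% ± 2.29 in BAP_70 and 1.71% ± 0.626 in BAP_40. Both BAP_70 libraries of set q were the highest, at 7.99% and 5.20%. In set q alone 3770 genes passed, 951 higher and 2819 lower, against 1440 in set p alone.

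The step from BAP_40 to BAP_70 was then compared with the step from TSC_CTB to TSC_STB, to ask how alike syncytiotrophoblast formation was in both models. The step of PSG3 was lower between the BAP fractions, with a difference in log2 FC of -6.17 (SE 0.41, adjusted p = 3.52e-13). The difference for IFI27 was -6.36 (SE 0.78, adjusted p = 1.09e-07). All 9 tested pregnancy-specific glycoprotein genes had a lower step (0 and 9 adjusted over the list alone; adjusted p = 6.37e-12, or adjusted p = 0.0234 with an estimated correlation), among them PSG6 (-5.54) and PSG2 (-5.24). These genes were high in hESC_BAPD7 of the other run, though levels from different runs may not be comparable. That run held no size fractions, so whether the difference extends to BAP in general was not tested. Of 23 interferon genes, 16 had a lower step and 7 did not pass (0 and 16 adjusted over the list alone; adjusted p = 2.07e-10, or adjusted p = 0.036 with an estimated correlation). ODAPH also had a lower step (-4.96). The largest opposite differences were 6.76 for CCKBR, 5.33 for TMPRSS2, 4.92 for PMEL, 4.85 for TMC5 and 4.80 for CA12. In limma, 2423 of 13618 genes had a step that differed, 1689 with a higher and 734 with a lower step between the BAP fractions. After median-of-ratios rescaling the numbers were 1134 and 1058.

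Across the 13618 genes, which are not independent replicates, the fold changes of both steps correlated with a Pearson r of 0.544 (jackknife SE over libraries 0.041) and a Spearman rho of 0.496. Without 1 library at a time r ranged from 0.520 to 0.558. The slope of the BAP step on the TSC step was 0.389. Of the genes called in both steps, 382 were higher in both against 53.8 expected by chance (Fisher's exact test, odds ratio 21.2, p = 5.70e-256). A further 403 were lower in both against 157.5 (odds ratio 5.77, p = 7.97e-99 by the same exact test, which takes genes as independent). Opposite directions were found for 49 of 834 genes. The balance depended on the scaling, with 577 higher and 55 lower in both after median-of-ratios rescaling and 525 and 86 after quantile normalisation. At pseudocounts of 0.25 and 5 CPM the numbers were 495 and 615, and 264 and 125.

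**Figure D2:**
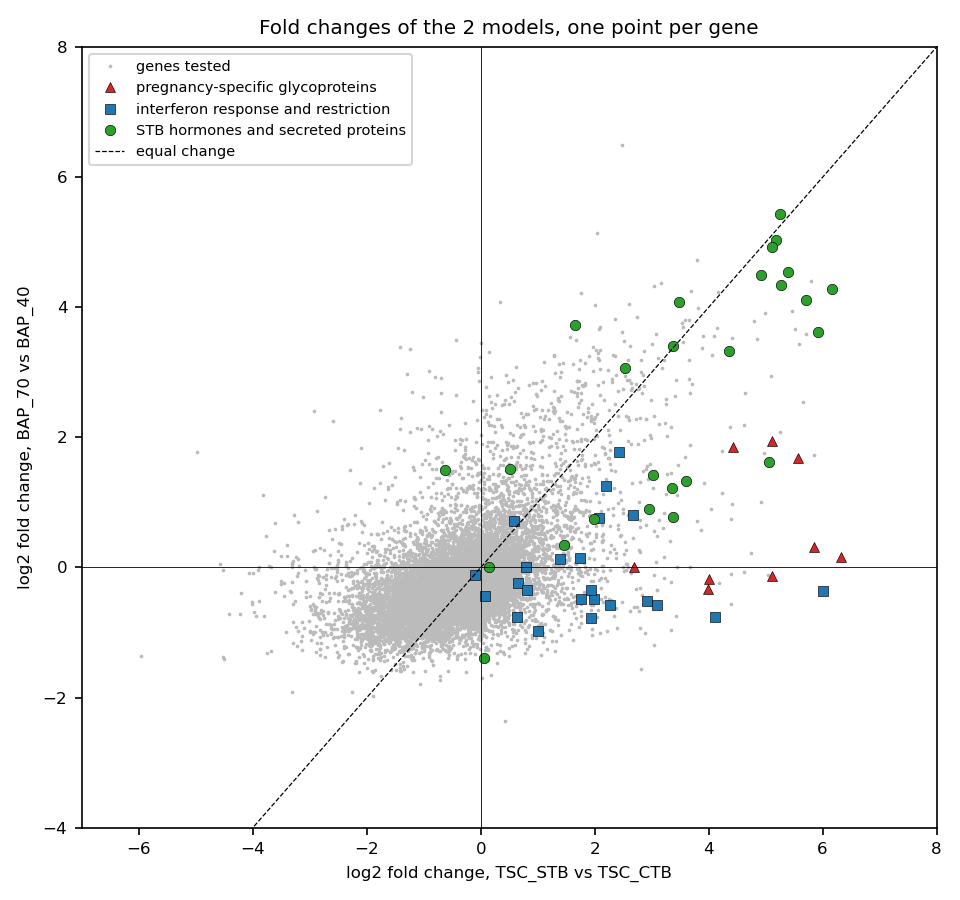
Log2 fold change of each tested gene from BAP_40 to BAP_70 (vertical axis) against that from TSC_CTB to TSC_STB (horizontal axis), on the log2(CPM + 1) scale. PSG3 lies at 6.33 on the horizontal and 0.16 on the vertical axis, and IFI27 at 6.00 and -0.36.

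BAP_70 was compared with TSC_STB (n = 7 and 6) to ask how syncytiotrophoblast from both models differed, and levels are given for BAP_70 against TSC_STB. PSG3 was at 1.50 ± 0.545 against 2040 ± 625 CPM (log2 FC -9.63) and PSG2 at 0.673 ± 0.661 against 755 ± 119 CPM (log2 FC -8.88). In the other run PSG3, PSG2, PSG6 and XAGE3 were high in hESC_BAPD7, with levels given below. Their low levels in BAP_70 therefore did not extend to all BAP-treated cells, though levels from different runs may not be comparable. The leptin gene LEP was at 5.22 ± 3.31 against 833 ± 266 CPM (log2 FC -7.22), and IFI27 at 1.80 ± 2.35 against 302 ± 214 CPM (log2 FC -6.78). The matrix gene SPARC was higher in BAP_70, at 1256 ± 394 against 154 ± 23.1 CPM (log2 FC 2.96), as was the type I collagen gene COL1A1, at 36.2 ± 6.34 against 3.34 ± 0.572 CPM (log2 FC 3.09). CGA did not pass, at 69285 ± 11984 against 129020 ± 28916 CPM (log2 FC -0.88, adjusted p = 0.0442).

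Of 9 pregnancy-specific glycoprotein genes, all 9 were lower (0 and 9 adjusted over the list alone; adjusted p = 9.41e-14, or adjusted p = 0.0114 with an estimated correlation), with log2 FC of -8.54 for PSG6 and -6.83 for PSG1. Of 26 STB hormone and secreted protein genes, 5 were higher, 13 lower and 8 did not pass (5 and 13 adjusted over the list alone; adjusted p = 0.000554, or adjusted p = 0.308 with an estimated correlation). CGB5 was at 2835 ± 953 against 15298 ± 4483 CPM (log2 FC -2.46) and GDF15 at 451 ± 237 against 2667 ± 891 CPM (log2 FC -2.66). The protease gene PAPPA2 was higher (log2 FC 2.79) and CGB1 lower (-2.87). The placental growth hormone gene GH2 was at 2.52 ± 1.22 against 12.5 ± 3.44 CPM (log2 FC -1.97), and GCM1 at 36.2 ± 6.36 against 103 ± 11.9 CPM (log2 FC -1.50). CSH1 did not pass, at 1.91 ± 1.01 against 2.40 ± 1.24 CPM (log2 FC -0.23, adjusted p = 0.424). CYP19A1 did not pass, at 1179 ± 230.0 against 2198 ± 677 CPM (log2 FC -0.87, adjusted p = 0.0397). Both CGA and CYP19A1 passed as lower after median-of-ratios rescaling (-1.22 and -1.21), and CGA without TSC_STB replicate p3 (-1.02). ERVW-1 was at 788 ± 126 against 941 ± 242 CPM (log2 FC -0.23, adjusted p = 0.498) and did not pass, nor did SDC1 at 2191 ± 990.0 against 1351 ± 423 CPM (log2 FC 0.66, adjusted p = 0.0663) and HSD3B1 at 2113 ± 403 against 1179 ± 212 CPM (log2 FC 0.84, adjusted p = 0.000757). In set q alone SDC1 (1.16) and HSD3B1 (1.18) passed as higher.

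Of 11 amnion markers, 9 were higher, 0 lower and 2 did not pass (9 and 0 adjusted over the list alone; adjusted p = 0.00462, or adjusted p = 0.304 with an estimated correlation). VTCN1 (chromosome 1, 117143587 to 117210960) was at 21.0 ± 8.36 against 0.188 ± 0.0750 CPM (log2 FC 4.09) and IGFBP3 at 35.8 ± 16.6 against 7.67 ± 5.46 CPM (log2 FC 2.21). ANXA8 (1.40) and BAMBI (1.47) were also higher. IGFBP3, ANXA8 and BAMBI did not pass in set q alone (0.08, 0.51 and 0.67). Of 22 genes of matrix and mesenchymal transition, 14 were higher, 0 lower and 8 did not pass (14 and 0 adjusted over the list alone; adjusted p = 0.000217, or adjusted p = 0.229 with an estimated correlation), with log2 FC of 3.39 for COL5A2 and 2.51 for COL5A1. Of 10 fibroblast and mesenchyme markers, 8 were higher, 0 lower and 2 did not pass (8 and 0 adjusted over the list alone; adjusted p = 0.000853, or adjusted p = 0.106 with an estimated correlation). TAGLN was at 90.7 ± 12.7 against 18.5 ± 9.29 CPM (log2 FC 2.35) and FBN1 at 21.4 ± 7.18 against 3.37 ± 1.63 CPM (log2 FC 2.38). LUM was higher at 9.32 ± 3.42 against 0.0246 ± 0.00206 CPM and VIM at 4.24 ± 0.650 against 0.0368 ± 0.0137 CPM, but VIM did not pass at a pseudocount of 5 CPM. The TSC_STB value of LUM was exactly 1 read in every library and may have been altered before the table was made. Of 23 interferon genes, 3 were higher, 10 lower and 10 did not pass (3 and 10 adjusted over the list alone; adjusted p = 0.00134, or adjusted p = 0.269 with an estimated correlation). ISG15 was at 80.3 ± 14.4 against 576 ± 183 CPM (log2 FC -2.79) and OAS2 was lower (-3.30). IFITM2, whose product restricts viral entry, was at 66.2 ± 16.6 against 1.19 ± 0.201 CPM (log2 FC 4.90).

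Among the largest differences, the long non-coding RNA UCA1 was at 0.239 ± 0.0623 against 509.9 ± 70.6 CPM (log2 FC -8.68) and XAGE3 at 0.252 ± 0.189 against 238 ± 45.1 CPM (log2 FC -7.57). IGFBP2 was at 459 ± 59.9 against 2.57 ± 1.45 CPM (log2 FC 7.08), with log2 FC of 5.52 for AADAT, 4.91 for ID4 and 4.78 for MAP1B. HLA-G passed as higher in BAP_70, at 184 ± 30.3 against 78.7 ± 85.2 CPM (log2 FC 3.39) with adjusted p = 0.0186. That call rested on TSC_STB set p, at 1.36 ± 1.82 CPM, against 156 ± 13.8 CPM in set q, with n = 3 each. HLA-G did not pass in set q alone (0.36), in edgeR (0.87), in DESeq2 (0.85) or without TSC_STB replicates p1 (2.70) or p2 (2.57). In limma, 3001 genes passed, 2134 higher and 867 lower in BAP_70, with a median of 0.27. After median-of-ratios rescaling 1393 were higher and 1338 lower. The mitochondrial share was 3.59% ± 2.29 in BAP_70 and 1.96% ± 0.856 in TSC_STB.

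BAP_40 was compared with TSC_CTB (n = 6 and 6) to ask how the small BAP fraction differed from cytotrophoblast, with the TSC_CTB sample labelled differentiated included, and levels are given for BAP_40 against TSC_CTB. SPARC was at 1627 ± 165 against 66.5 ± 12.1 CPM (log2 FC 4.61). TAGLN, an actin-binding protein gene of smooth muscle and mesenchyme, was at 167 ± 12.7 against 6.31 ± 2.34 CPM (log2 FC 4.59), and VTCN1 at 32.1 ± 9.36 against 0.222 ± 0.162 CPM (log2 FC 4.72). TP63 was lower, at 1.07 ± 0.290 against 12.5 ± 2.77 CPM (log2 FC -2.69). The trophoblast transcription factor gene TFAP2C was at 67.8 ± 8.55 against 365 ± 43.8 CPM (log2 FC -2.41) and TEAD4 at 15.6 ± 1.93 against 66.7 ± 10.2 CPM (log2 FC -2.02). GATA3 (chromosome 10, 8045378 to 8075203) did not pass, at 292 ± 24.1 against 466 ± 42.8 CPM (log2 FC -0.67, adjusted p = 1.25e-06).

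Of 11 amnion markers, 10 were higher, 0 lower and 1 did not pass (10 and 0 adjusted over the list alone; adjusted p = 5.34e-05, or adjusted p = 0.177 with an estimated correlation). IGFBP3 was at 60.9 ± 41.1 against 0.0875 ± 0.0892 CPM (log2 FC 5.51), with log2 FC of 2.52 for ANXA8 and 2.05 for WNT6. ISL1 was higher at 3.87 ± 1.31 against 0.497 ± 0.125 CPM (log2 FC 1.66), but did not pass at a pseudocount of 5 CPM. GABRP was not tested, at 1.05 ± 0.341 against 0.0236 ± 0.00148 CPM. Of 22 genes of matrix and mesenchymal transition, 17 were higher, 1 lower and 4 did not pass (17 and 1 adjusted over the list alone; adjusted p = 1.04e-05, or adjusted p = 0.177 with an estimated correlation). The basement membrane collagen gene COL4A1 was at 665 ± 194 against 92.0 ± 20.7 CPM (log2 FC 2.80), and COL1A1 was higher (4.00). VIM was higher, at 6.33 ± 0.511 against 0.0236 ± 0.00148 CPM. The TSC_CTB values of VIM and GABRP were exactly 1 read in every library, a level that may have been altered before the table was made. Of 10 fibroblast and mesenchyme markers, 9 were higher, 1 lower and 0 did not pass (9 and 1 adjusted over the list alone; adjusted p = 9.46e-05, or adjusted p = 0.0789 with an estimated correlation), with log2 FC of 4.81 for FBN1, 3.83 for LUM and 2.77 for CNN1.

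Of 20 CTB and trophoblast stem cell markers, 3 were higher, 11 lower and 6 did not pass (3 and 11 adjusted over the list alone; adjusted p = 0.00185, or adjusted p = 0.289 with an estimated correlation). LRP2 was at 6.38 ± 1.31 against 261 ± 58.6 CPM (log2 FC -5.13) and PEG10 at 49.4 ± 9.98 against 682 ± 186 CPM (log2 FC -3.74), with log2 FC of -2.81 for FZD5 and -2.71 for PAGE4. The stem cell transcription factor gene ELF5 was lower at 0.0656 ± 0.109 against 4.54 ± 2.53 CPM, but did not pass at a pseudocount of 5 CPM. Of 18 fusion and STB regulators, 2 were higher, 12 lower and 4 did not pass (2 and 12 adjusted over the list alone; adjusted p = 0.000315, or adjusted p = 0.205 with an estimated correlation). GCM1 was at 5.44 ± 1.61 against 72.0 ± 24.4 CPM (log2 FC -3.46), with log2 FC of -5.43 for ERVMER34-1, -3.84 for ERVV-2 and -3.67 for ERVH48-1. Among the largest differences, AADAT was at 287 ± 80.4 against 1.14 ± 0.342 CPM (log2 FC 7.04) and SERPINE2 at 232 ± 82.8 against 1.68 ± 0.4662 CPM (log2 FC 6.38), with log2 FC of 6.07 for IFITM2, 5.81 for MAP1B and 5.74 for ID4. UCA1 was at 0.389 ± 0.127 against 486 ± 86.9 CPM (log2 FC -8.44), and XAGE3 (-6.95) and GTSF1 (-6.49) were lower. BRDT was lower at 0.0645 ± 0.0767 against 127 ± 10.9 CPM and FABP7 at 0.0739 ± 0.0452 against 95.4 ± 13.1 CPM. MKI67 did not pass, at 86.4 ± 46.6 against 99.7 ± 24.3 CPM (log2 FC -0.36, adjusted p = 0.3), nor did ITGA6 (-0.19, adjusted p = 0.436). POU5F1, not tested, was at 0.00945 ± 0.0146 CPM in BAP_40 and 0 CPM in TSC_CTB. HLA-G had a log2 FC of 1.28 (adjusted p = 0.386) although its mean was lower in BAP_40, at 70.5 ± 10.4 against 127 ± 144 CPM. Within the column sets it was 4.31 in set p and -1.75 in set q. In limma, 3942 genes passed, 2158 higher and 1784 lower in BAP_40, with a median of 0.06. After median-of-ratios rescaling 1862 were higher and 1900 lower, so the direction of the majority turned. The mitochondrial share was 1.71% ± 0.626 in BAP_40 and 0.666% ± 0.114 in TSC_CTB.

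**Figure D3:**
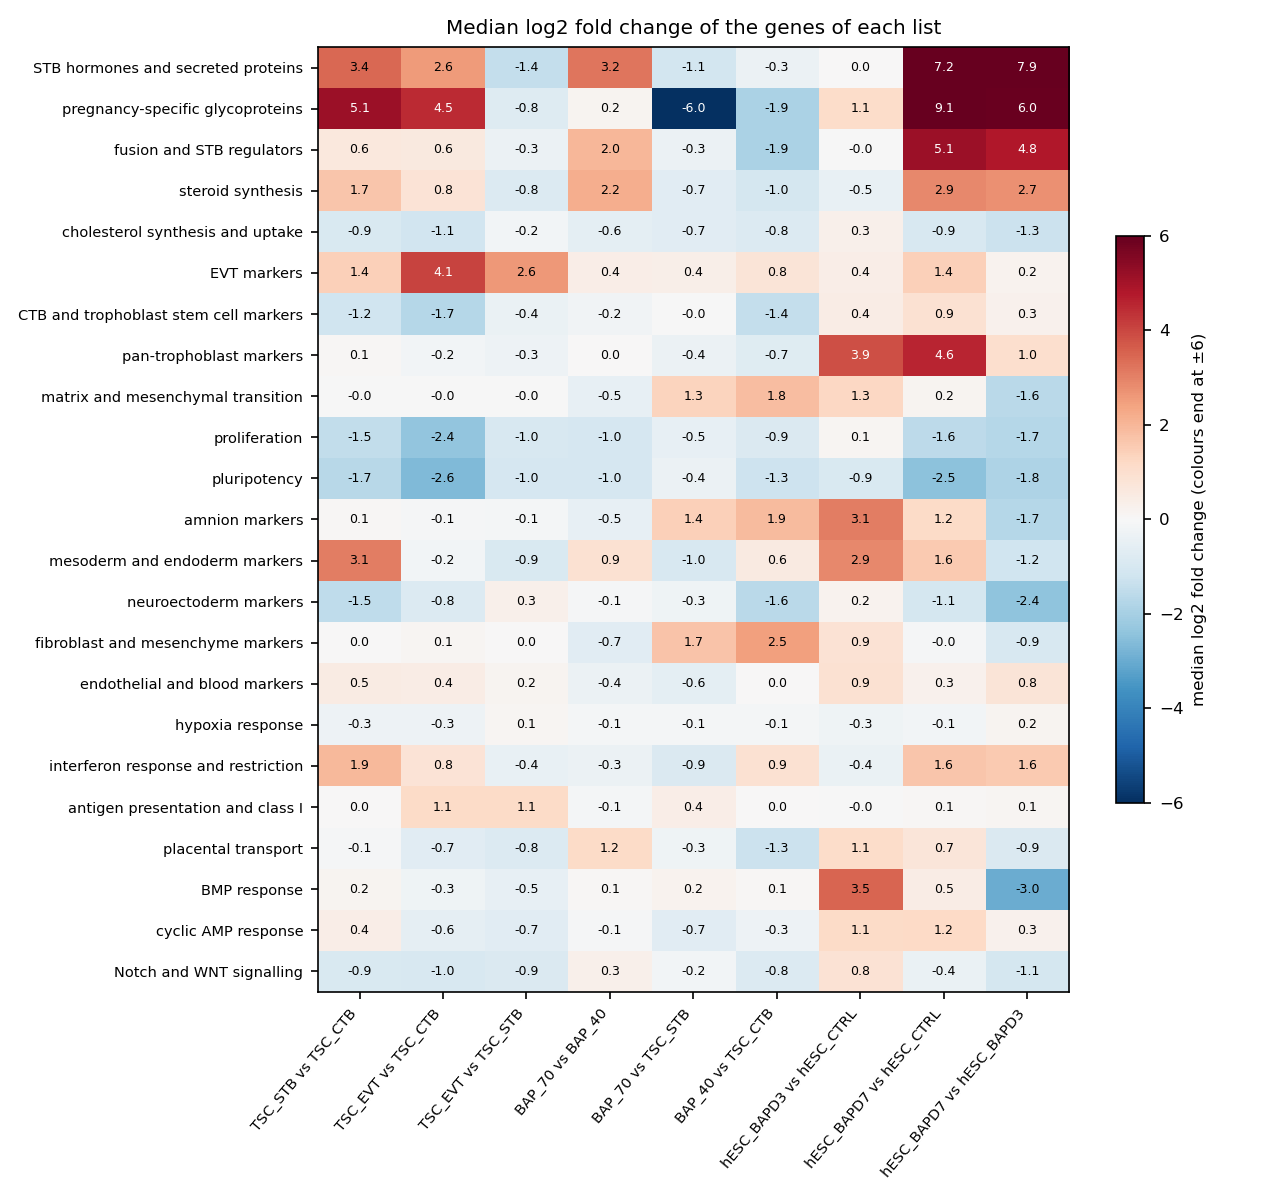
Median log2 fold change of the genes of each list (rows) in each comparison (columns), on the log2(CPM + 1) scale. Colours end at -6 and 6, and genes at 0 in a group depend on the pseudocount and give no bound.

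Whole profiles of the hESC-derived groups were compared with the mean profiles of the 3 TSC groups over 13618 genes, to ask which TSC state each lay nearest. The BAP_70 libraries had a mean Spearman rho of 0.906 with TSC_STB, 0.882 with TSC_EVT and 0.850 with TSC_CTB, and TSC_STB was the highest in 7 of 7. BAP_40 had 0.875 with TSC_CTB and 0.864 with both others, and TSC_CTB was the highest in 6 of 6. For BAP_40 the difference of TSC_STB minus TSC_EVT was 0.000737, but -0.00045 without BAP_40 replicate p1 and -8.09e-06 without p3. It was negative in 3 of 3 libraries of set q (mean -0.00241) and positive in 3 of 3 of set p (mean 0.00388). hESC_BAPD7 had 0.931 with TSC_STB, 0.904 with TSC_EVT and 0.874 with TSC_CTB. hESC_BAPD3 had 0.847 with TSC_CTB, 0.846 with TSC_STB and 0.816 with TSC_EVT. For hESC_BAPD3 the difference of TSC_CTB minus TSC_STB was 0.00129, and -0.00702 with a filter of 5 CPM. hESC_CTRL had 0.842 with TSC_CTB, 0.818 with TSC_STB and 0.800 with TSC_EVT. None of the 15 differences could pass an exact sign-flip test after adjustment, since the lowest adjusted p that 15 such exact tests allow is 0.0781 for BAP_70 and BAP_40 and 0.25 for the groups of 3. The exact p was the smallest possible for all 3 differences of BAP_70 (0.0156, adjusted p = 0.0781) and for both with TSC_CTB of BAP_40 (0.0312, adjusted p = 0.0938). The 3 groups of the hESC run were compared with TSC profiles of the other run.

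**Figure D4:**
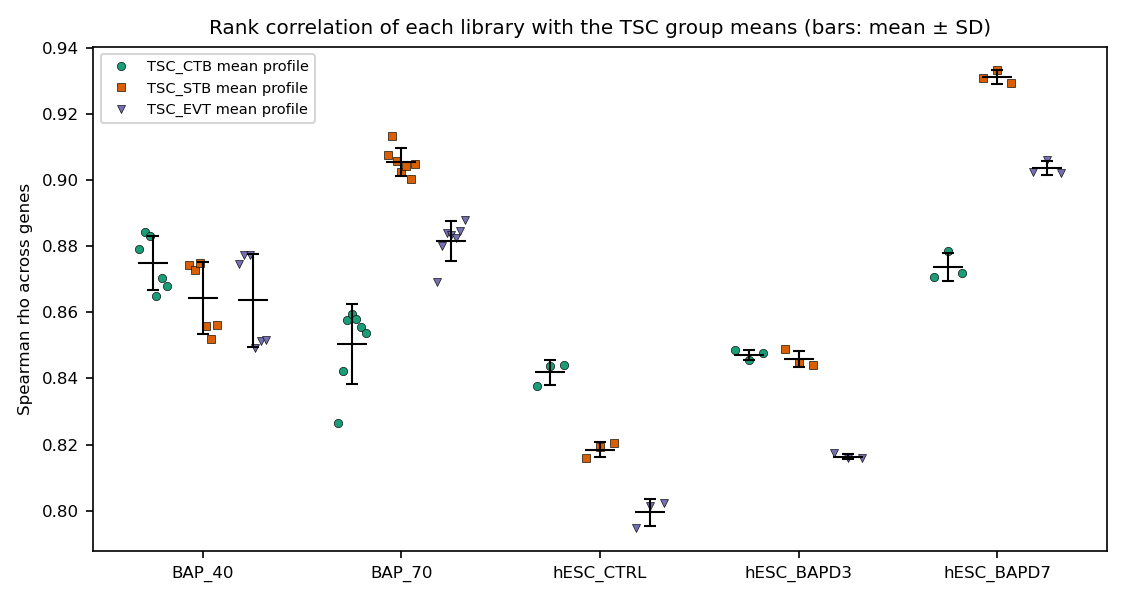
Spearman rho between each hESC-derived library and the mean profile of each TSC group, with points for libraries and bars for means ± SD. The 7 BAP_70 and the 3 hESC_BAPD7 libraries lie highest with TSC_STB, at means of 0.906 and 0.931.

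The comparison of hESC_BAPD3 with the libraries labelled hESC_CTRL (n = 3 and 3) asked what changed first under BAP. The trophoblast and amnion transcription factor gene GATA3 rose from 0.529 ± 0.248 to 127 ± 13.97 CPM (log2 FC 6.3997, SE 0.19, adjusted p = 2.12e-10). TFAP2A rose from 0.213 ± 0.126 to 104 ± 5.18 CPM. KRT7 (chromosome 12, 52232520 to 52252186), an epithelial keratin gene, rose from 36.5 ± 6.53 to 1642 ± 85.5 CPM (log2 FC 5.47, SE 0.18, adjusted p = 4.44e-10). The BMP target gene MSX2 rose from 0.477 ± 0.348 to 130.0 ± 7.85 CPM (log2 FC 6.50), and ID1 from 14.5 ± 6.67 to 138 ± 14.1 CPM (log2 FC 3.26). NANOG fell from 10.9 ± 1.34 to 0.500 ± 0.260 CPM (log2 FC -2.99). CGA was at 0 CPM in hESC_CTRL and 0.116 ± 0.00130 CPM at day 3, or 1 read per library.

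Of 19 pan-trophoblast markers, 15 rose, 0 fell and 4 did not pass (15 and 0 adjusted over the list alone; adjusted p = 1.20e-06, or adjusted p = 0.269 with an estimated correlation). TACSTD2 rose from 0.383 ± 0.176 to 81.1 ± 9.07 CPM (log2 FC 5.89), with log2 FC of 5.68 for GRHL3 and 5.03 for TFAP2C. Of 14 BMP response genes, 13 rose, 0 fell and 1 did not pass (13 and 0 adjusted over the list alone; adjusted p = 1.19e-05, or adjusted p = 0.269 with an estimated correlation). BMP4 rose from 0.607 ± 0.203 to 67.6 ± 11.7 CPM (log2 FC 5.41), and DLX5 from 0.120 ± 0.0855 to 259.9 ± 33.6 CPM. Of 9 amnion markers, all 9 rose (9 and 0 adjusted over the list alone; adjusted p = 3.67e-05, or adjusted p = 0.0816 with an estimated correlation). BAMBI rose from 1.88 ± 0.802 to 59.1 ± 5.89 CPM (log2 FC 4.42), with log2 FC of 3.59 for HEY1 and 3.61 for IGFBP3. WNT6 rose from 0.0735 ± 0.0796 to 35.1 ± 3.91 CPM and ISL1 from 0.0451 ± 0.0394 to 2.66 ± 0.207 CPM, but ISL1 did not pass at a pseudocount of 5 CPM. Of 5 mesoderm and endoderm markers, 3 rose, 0 fell and 2 did not pass (3 and 0 adjusted over the list alone; adjusted p = 0.104, or adjusted p = 0.357 with an estimated correlation), and the list did not pass as deposited, but did after median-of-ratios rescaling (adjusted p = 0.0142). GATA6 rose from 0.0922 ± 0.0285 to 30.5 ± 2.05 CPM. The apolipoprotein gene APOA1 rose from 0.293 ± 0.441 to 92.9 ± 75.3 CPM (log2 FC 5.45), and the transthyretin gene TTR from 0 to 10.3 ± 10.2 CPM. Not tested were GABRP (0.0714 ± 0.00835 to 0.309 ± 0.0653 CPM), CDX2 (0.0714 ± 0.00835 to 0.927 ± 0.0104 CPM) and TBXT (0.499 ± 0.134 to 0.230 ± 0.197 CPM). TP63 did not pass (0.0451 ± 0.0394 to 0.271 ± 0.136 CPM, adjusted p = 0.124).

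Of 16 pluripotency genes, 0 rose, 7 fell and 9 did not pass (0 and 7 adjusted over the list alone; adjusted p = 8.08e-11, or adjusted p = 0.125 with an estimated correlation), and 11 fell after median-of-ratios rescaling. LEFTY1 fell from 2074 ± 809.8 to 0 CPM. The telomere protein gene TERF1 fell from 243 ± 28.4 to 93.7 ± 8.32 CPM (log2 FC -1.36), and the DNA methyltransferase gene DNMT3B from 174 ± 23.0 to 69.8 ± 7.67 CPM (log2 FC -1.31). POU5F1 did not pass (1.91 ± 0.259 to 0.579 ± 0.110 CPM, log2 FC -0.88, adjusted p = 0.000111), but passed after median-of-ratios rescaling (-1.07). SOX2, not tested, was at 0.593 ± 0.119 CPM in hESC_CTRL and 0.348 ± 0.00389 CPM at day 3. DPPA5 (chromosome 6, 73353062 to 73354295), a gene of pluripotent cells, fell from 147360 ± 87391 to 0 CPM, and FGF21 from 63183 ± 17370 to 0 CPM. GABRR1, SUPT20HL2 and AZGP1 fell to 0 CPM from 8672 ± 3780, 7560 ± 6082 and 4514 ± 4156 CPM. The 10 highest genes of a hESC_CTRL library took 22.9% to 39.0% of its reads. Among the largest rises, CYP1B1 rose from 0.508 ± 0.165 to 328 ± 51.4 CPM (log2 FC 7.76) and ANXA1 from 5.26 ± 5.28 to 1047 ± 90.6 CPM (log2 FC 7.70), with log2 FC of 7.17 for ABCG2 and 6.94 for FLNC. In limma, 4118 of 13498 genes passed, 3493 higher and 625 lower at day 3, with a median of 0.58. After median-of-ratios rescaling 2462 passed, 1215 higher and 1247 lower.

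hESC_BAPD7 was compared with hESC_CTRL (n = 3 and 3) to ask what marked the end of the protocol. CGA rose from 0 to 373310 ± 26424 CPM (adjusted p = 1.03e-16), and CGB5 from 0.0263 ± 0.0456 to 28728 ± 6761 CPM (adjusted p = 3.32e-14). ERVW-1 rose from 1.55 ± 0.201 to 2267 ± 145 CPM (log2 FC 9.80). HSD3B1 rose from 0 to 2878 ± 28.1 CPM and PSG3 from 0 to 2190 ± 437 CPM. TERF1 fell from 243 ± 28.4 to 5.47 ± 0.539 CPM (log2 FC -5.23), and NANOG from 10.9 ± 1.34 to 0 CPM.

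Of 21 STB hormone and secreted protein genes, 17 rose, 1 fell and 3 did not pass (17 and 1 adjusted over the list alone; adjusted p = 2.41e-16, or adjusted p = 0.0182 with an estimated correlation). CGB8 rose from 0 to 18585 ± 3770 CPM and CGB3 from 0 to 16944 ± 4570 CPM. Of 9 pregnancy-specific glycoprotein genes, all 9 rose (9 and 0 adjusted over the list alone; adjusted p = 8.93e-12, or adjusted p = 0.00745 with an estimated correlation). PSG4 rose from 0 to 1930 ± 85.8 CPM, PSG2 from 0 to 1020 ± 61.9 CPM and PSG6 from 0 to 996 ± 305 CPM. Of 19 pan-trophoblast markers, 18 rose, 0 fell and 1 did not pass (18 and 0 adjusted over the list alone; adjusted p = 5.83e-19, or adjusted p = 0.0475 with an estimated correlation). GATA2 rose from 0.431 ± 0.259 to 598 ± 129.7 CPM (log2 FC 8.70), with log2 FC of 6.79 for TFAP2C, 7.41 for GATA3 and 3.07 for KRT7. XAGE2 rose from 0.0242 ± 0.0420 to 1525 ± 94.7 CPM, VGLL1 from 0.146 ± 0.253 to 436 ± 86.0 CPM and XAGE3 from 0 to 186 ± 57.8 CPM. TFAP2A rose from 0.213 ± 0.126 to 28.3 ± 2.60 CPM and TP63 from 0.0451 ± 0.0394 to 4.24 ± 0.842 CPM, but TP63 did not pass at a pseudocount of 5 CPM. HLA-G rose by 5.39 on the log2 scale. Of 9 amnion markers, 5 rose, 0 fell and 4 did not pass (5 and 0 adjusted over the list alone; adjusted p = 0.000342, or adjusted p = 0.0451 with an estimated correlation). HEY1 rose from 5.51 ± 1.10 to 66.4 ± 23.6 CPM (log2 FC 3.32), IGFBP3 from 0.355 ± 0.0705 to 5.78 ± 0.881 CPM (log2 FC 2.32) and WNT6 from 0.0735 ± 0.0796 to 7.59 ± 1.46 CPM. ISL1 did not pass (0.0451 ± 0.0394 to 0.122 ± 0.0282 CPM, adjusted p = 0.433). Not tested were GABRP (0.0714 ± 0.00835 to 0.167 ± 0.0282 CPM), TBXT (0.499 ± 0.134 to 0.0619 ± 0.0719 CPM) and CDX2 (0.0714 ± 0.00835 to 0.0455 ± 0.00123 CPM).

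Of 16 pluripotency genes, all 16 fell (0 and 16 adjusted over the list alone; adjusted p = 3.29e-05, or adjusted p = 0.129 with an estimated correlation). DPPA4 fell from 101 ± 12.0 to 7.50 ± 1.03 CPM (log2 FC -3.58). TDGF1 fell from 25.5 ± 6.50 to 0.0455 ± 0.00123 CPM and LEFTY1 from 2074 ± 809.8 to 0 CPM. POU5F1 fell from 1.91 ± 0.259 to 0.335 ± 0.0792 CPM (log2 FC -1.12), but did not pass after median-of-ratios rescaling (-0.83). SOX2, not tested, was at 0.593 ± 0.119 CPM in hESC_CTRL and 0.0455 ± 0.00123 CPM at day 7. DPPA5, FGF21, GABRR1, SUPT20HL2 and AZGP1 were at 0 CPM in all day 7 libraries and fell. Of 26 proliferation genes, 0 rose, 21 fell and 5 did not pass (0 and 21 adjusted over the list alone; adjusted p = 0.0004, or adjusted p = 0.448 with an estimated correlation), but after median-of-ratios rescaling 1 rose and 8 fell. BUB1 fell from 98.4 ± 11.3 to 12.0 ± 0.839 CPM (log2 FC -2.94), with log2 FC of -2.29 for PCNA, -2.17 for BIRC5 and -2.16 for MCM3. In limma, 6481 genes passed, 1630 higher and 4851 lower at day 7, with a median of -0.66. After median-of-ratios rescaling 2967 were higher and 1907 lower.

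hESC_BAPD7 was also compared with hESC_BAPD3 (n = 3 and 3) to follow the change between both days. CGA rose from 0.116 ± 0.00130 to 373310 ± 26424 CPM and CGB5 from 0.0770 ± 0.0667 to 28728 ± 6761 CPM. The BMP target gene ID3 fell from 1027 ± 119 to 19.8 ± 3.61 CPM (log2 FC -5.63), and BAMBI from 59.1 ± 5.89 to 0.989 ± 0.274 CPM (log2 FC -4.92). The interferon-response gene ISG15 rose from 4.31 ± 1.81 to 304 ± 48.8 CPM (log2 FC 5.89). HLA-G rose from 0.540 ± 0.172 to 139 ± 34.1 CPM (log2 FC 6.48). The placental growth factor gene PGF rose from 0.116 ± 0.00130 to 5513 ± 623 CPM.

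Of 21 STB hormone and secreted protein genes, 17 rose, 1 fell and 3 did not pass (18 and 1 adjusted over the list alone; adjusted p = 3.39e-25, or adjusted p = 0.00544 with an estimated correlation). CGB8 rose from 0 to 18585 ± 3770 CPM and CGB3 from 0 to 16944 ± 4570 CPM. ERVW-1 rose from 0.116 ± 0.00130 to 2267 ± 145 CPM. Of 14 BMP response genes, 1 rose, 11 fell and 2 did not pass (1 and 11 adjusted over the list alone; adjusted p = 0.24, or adjusted p = 0.681 with an estimated correlation), and the list did not pass as deposited, but did after median-of-ratios rescaling (adjusted p = 0.00724). BMP4 fell from 67.6 ± 11.7 to 2.25 ± 0.958 CPM (log2 FC -4.43). SMAD6, which encodes an inhibitor of BMP signalling, fell from 16.3 ± 0.438 to 0.334 ± 0.0580 CPM (log2 FC -3.70). Of 9 amnion markers, 0 rose, 7 fell and 2 did not pass (0 and 7 adjusted over the list alone; adjusted p = 0.186, or adjusted p = 0.308 with an estimated correlation), and the list did not pass. After median-of-ratios rescaling 1 rose and 4 fell. IGFBP3 (-1.30) and VTCN1 (-1.18) fell as deposited, but stood at 0.13 and 0.13 after that rescaling. WNT6 (-2.08) fell and did not pass after it (-0.60). Of 22 interferon genes, 15 rose, 2 fell and 5 did not pass (15 and 2 adjusted over the list alone; adjusted p = 3.05e-15, or adjusted p = 0.0617 with an estimated correlation). IFI6 rose from 0.116 ± 0.00130 to 225 ± 28.99 CPM, MX1 from 0.116 ± 0.00130 to 45.1 ± 4.98 CPM and IFIT1 from 0.231 ± 0.113 to 44.5 ± 12.2 CPM. TP63 rose from 0.271 ± 0.136 to 4.24 ± 0.842 CPM, but did not pass at a pseudocount of 5 CPM. MKI67 fell with a log2 FC of -1.51, but stood at 0.03 after median-of-ratios rescaling. CDX2, not tested, was at 0.927 ± 0.0104 CPM at day 3 and 0.0455 ± 0.00123 CPM at day 7. Among the largest falls, CYP1B1 fell from 328 ± 51.4 to 0.637 ± 0.133 CPM (log2 FC -7.64) and FLNC from 202 ± 34.8 to 0.778 ± 0.302 CPM (log2 FC -6.83), with log2 FC of -7.12 for GLRX and -6.79 for CLDN10. ALPL fell from 104 ± 9.67 to 0.0910 ± 0.00247 CPM.

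In limma, 9192 genes passed, 1136 higher and 8056 lower at day 7, with a median of -1.25. After median-of-ratios rescaling 4678 passed, 2839 higher and 1839 lower, so the direction of the majority turned with the scaling. In both comparisons that include day 7, sequencing lane and group cannot be told apart, since day 7 was read on a lane of its own. The share of mitochondrial reads was 5.16% ± 0.285 in hESC_CTRL, 3.00% ± 0.927 in hESC_BAPD3 and 2.71% ± 0.874 in hESC_BAPD7.

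**Figure D5:**
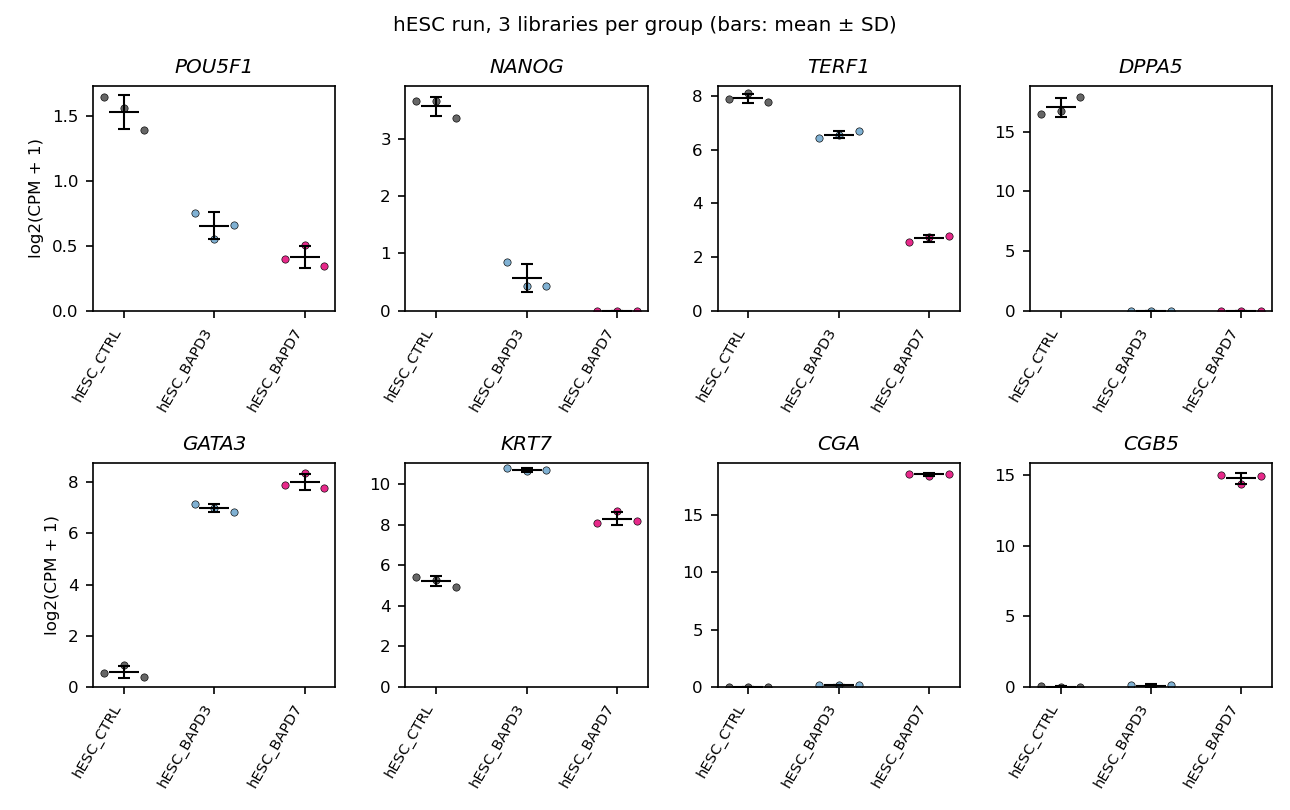
Log2(CPM + 1) of marker genes in the 3 libraries each of hESC_CTRL, hESC_BAPD3 and hESC_BAPD7, with points for libraries and bars for group means ± SD. GATA3 rises from 0.529 CPM to 127 CPM at day 3 and 261 CPM at day 7.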

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

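In this part the tests of a step that keeps whole numbers, of cells that had left the pluripotent state and of a change of each gene by a factor of its own were chosen after the result they address was seen.

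A library far from the others of its group was looked for with Dixon's Q in 351 sets of values, and 11 were found where chance, at about 1 in 20 groups, would give 17.6. The share of a library's total held by the table was low in 1 BAP_70 library, at 96.36% against 98.18% for the next (Q 0.643). For genes, values are log2(CPM + 1) of the extreme library and of its nearest neighbour. PHLDA2 in BAP_40 had 1 high library at 4.354 against 0.03709 (Q 0.991), and CGB1 in BAP_70 had 3.093 against 1.466 (Q 0.687). In TSC_CTB, PSG4 had a low library at 3.17 against 4.424 (Q 0.697) and PSG6 at 2.626 against 3.829 (Q 0.754). In TSC_EVT, SLC22A11 had a low library at 4.213 against 4.663 (Q 0.663) and TOP2A a high one at 5.008 against 4.735 (Q 0.745). In TSC_STB, AADAT had a high library at 2.908 against 2.243 (Q 0.665) and ANPEP at 3.378 against 2.791 (Q 0.739). GH2 had a low library there at 2.83 against 3.641 (Q 0.668) and MFSD2A at 4.823 against 5.757 (Q 0.63).

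A difference between the models drew attention to 2423 genes whose step from BAP_40 to BAP_70 differed from the step from TSC_CTB to TSC_STB, tested with an interaction term in limma. The largest differences in log2 fold change were -6.36 for IFI27, -6.17 for PSG3, -5.54 for PSG6, -5.24 for PSG2 and -4.96 for ODAPH. In the other direction they were 6.76 for CCKBR, 5.33 for TMPRSS2, 4.92 for PMEL, 4.85 for TMC5 and 4.80 for CA12. When libraries were relabelled within each model, 2 of 100 relabellings, the real one included, called as many genes. The real labels called 2407 genes in that fit, and 1 other relabelling called 3095. The relabelling breaks up the steps themselves, so it bears on libraries grouped without any step in either model and not on equal steps in both. Which labels were exchanged in the relabelling that called more genes was not examined, so the reason for its higher number stays open.

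The same was done for the numbers of genes that passed between groups, in fits on the compared groups alone. For TSC_STB and TSC_CTB 1 of 100 splits, the real one, reached 4287 genes, and the highest other split reached 2171. It was also 1 of 100 for TSC_EVT and TSC_CTB (3624, highest other 1567), TSC_EVT and TSC_STB (2384 and 970), BAP_70 and BAP_40 (1403 and 457), BAP_70 and TSC_STB (2997 and 1555) and BAP_40 and TSC_CTB (3930 and 1656). For the hESC run the 10 splits of 3 and 3 libraries are too few for a share under 0.05. There 1 split, the real one, reached 4102 genes for hESC_BAPD3 and hESC_CTRL (highest other 1), 6493 for hESC_BAPD7 and hESC_CTRL (highest other 0) and 9185 for hESC_BAPD7 and hESC_BAPD3 (highest other 0).

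Many genes stood at exactly 1 read in every library of an hESC group, and 57 did so in TSC_CTB, 46 in TSC_EVT and 40 in TSC_STB. Over genes with a mean of 1 to 5 reads, the summed variance was 1.177 times the summed mean in the lowest group, hESC_BAPD7, so it did not fall below the 1 of counting noise and this test alone left plain counts possible. The number of genes at exactly 1 argues against plain counts in hESC_BAPD7, at 1611 where counting noise allows at most 1090. The numbers in hESC_BAPD3 (1083, with at most 1090) and hESC_CTRL (824, with at most 1060) were within that limit. The limit is loose, since it takes every gene above 0 to have a mean of 1 read. At least 12727 genes in each hESC_BAPD3 library and 11886 in each hESC_CTRL library reached 1 CPM, which was more than 1 read. Most of the 21793 genes above 0 in hESC_BAPD3, and of the 21330 in hESC_CTRL, could therefore not stand at 1 in every library. For the other genes alone the limit falls below 1083 and 824, which argues against plain counts in these groups too. A step that keeps whole numbers and leaves positive values at 1 or more would give such an excess, and what it was stays open.

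POU5F1 (1.91 CPM) and SOX2 (0.593 CPM) were low in the libraries labelled hESC_CTRL, where DPPA5 stood at 147360 CPM. The highest genes do not account for it, since POU5F1 rose only to 2.66 CPM with the 10 highest genes of each library out of the totals. The other tested pluripotency genes, without NANOG, had a median of 42.22 CPM, against 11.16 CPM at day 3 and 2.768 CPM at day 7. This cannot tell whether most cells had left pluripotency, since genes too low to test were left out and others may have been altered. A change of each gene by a factor of its own before the table could give a ratio of 933.4 or more between the highest and lowest pluripotency gene in a library and an order kept between libraries (rank correlation 0.9824 or more). So could real differences between these genes, so that this stays open.

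Most genes were lower at day 7 than at day 3, with a median log2 fold change of -1.25. With CGA out of the totals the median was -0.745, and with the 10 highest genes of each library out it was -0.66, so these genes may explain part of it but not all. Of 4 groups of genes by day 3 level, the lowest lay 0.989 above the highest (bootstrap interval 0.932 to 1.05). This decides nothing on compression of low values, since the bound set beforehand took low genes to fall most, whereas compression shrinks their changes. Compression, a change in the RNA content of the cells, the sequencing lane and the step behind the whole numbers stay open.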

How the results depend on the processing

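The column sets as a block or each set alone, the fits without genes held at 1 read and the leave-one-out and column sets of profile similarity were chosen after the data were seen, and the other alternatives before.

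Of 323 results for single genes, 286 kept their side of the threshold under all alternatives, and 281 of these also kept their sign. Under at least 1 alternative 23 lost the call and 14 gained it. In all, 9 changed sign, 4 of them with a call before or after. HLA-G in BAP_40 against TSC_CTB, with a log2 fold change of 1.28, turned to -1.747 in set q alone and was 4.31 in set p alone. It was also negative, with no call, in edgeR (-0.9951) and DESeq2 (-0.9479). From day 3 to day 7 IGFBP3 (-1.30) turned to 0.1255 with median-of-ratios rescaling, 0.0395 with TMM, 0.06301 in edgeR and 0.1456 in DESeq2. VTCN1 (-1.18) turned to 0.1272, 0.04796, 0.07302 and 0.1561 under the same alternatives. MKI67 (-1.51) turned to 0.03053 with median-of-ratios rescaling and 0.03115 in DESeq2. These 3 turned only where the scaling was changed, and for HLA-G the cause of the difference between the sets was not tested. The other 5 were never called. They were HLA-G in TSC_STB against TSC_CTB (-0.739, at most 0.0788), ITGA6 (-0.194, at most 0.0933) and MKI67 (-0.357, at most 0.149) in BAP_40 against TSC_CTB, CSH1 in BAP_70 against TSC_STB (-0.231, at most 0.0446) and TP63 in BAP_70 against BAP_40 (0.0186, at least -0.0737).

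The numbers of genes that passed moved by less than 1.5 times under most alternatives. With no fold threshold, which can only add genes, they were 9664 for TSC_STB and TSC_CTB (4287 before), 8956 for TSC_EVT and TSC_CTB (3624) and 7745 for TSC_EVT and TSC_STB (2388). They were 8346 for BAP_70 and BAP_40 (1419), 8758 for BAP_70 and TSC_STB (3001), 9375 for BAP_40 and TSC_CTB (3942) and 6298 for the difference between models (2423). In the hESC run they were 9100 for day 3 and control (4118) and 10377 for day 7 and control (6481). A pseudocount of 5 CPM shrinks fold changes of low genes. In the same order it gave 2751, 2279, 1398, 739, 1369, 2266, 1441, 2379 and 3959 genes. For BAP_70 and BAP_40, set q alone gave 3770 genes, and the cause was not tested. For day 3 and control, median-of-ratios rescaling gave 2462, TMM 2500 and quantile normalisation 2589. For day 7 and day 3 (9192), they gave 4678, 4756 and 4905, edgeR 5898 and DESeq2 5639. These moved with the scaling. For day 7 and day 3, 6977 genes passed with CGA out of the totals and 6653 with the 10 highest genes of each library out, so these genes may account for part of the shift. For day 3 and control the cause was not tested.

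Without 1 library at a time, the numbers ranged from 4154 to 4459 for TSC_STB and TSC_CTB, 3554 to 3710 for TSC_EVT and TSC_CTB, 2281 to 2443 for TSC_EVT and TSC_STB, 1269 to 1589 for BAP_70 and BAP_40, 2911 to 3132 for BAP_70 and TSC_STB and 3904 to 3982 for BAP_40 and TSC_CTB. They ranged from 2357 to 2627 for the difference between models, 3721 to 4520 for day 3 and control, 6221 to 6919 for day 7 and control and 9074 to 9348 for day 7 and day 3. With letters A, B and C as replicate blocks in the hESC run, 4127, 6491 and 9198 genes passed. Residuals correlated between same letters by -0.145 to 0.147, so no strong shared effect of a letter was seen. This cannot tell whether the letters pair the libraries, since each group has only 3 and the labels do not say what the letters mark. With the column sets as a block, 4299, 3630, 2395, 1466, 2933, 3949 and 2464 genes passed in the order of the TSC and BAP run.

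Of 230 list tests, 115 passed with the preset correlation, 102 with median-of-ratios rescaling and 23 with an estimated correlation, which lost 92. The correlation of both steps stayed between 0.52711 and 0.56863 over other choices and between 0.52027 and 0.55755 without 1 library. Of the profile similarities, the difference of TSC_CTB minus TSC_STB for hESC_BAPD3 turned from 0.00129 to -0.00702 with a filter of 5 CPM. That of TSC_STB minus TSC_EVT for BAP_40 (0.000737) ranged from -0.00045 to 0.00181 without 1 library. It followed the column sets, at -0.00241 in set q and 0.00388 in set p. The cause was not tested for hESC_BAPD3, nor what sets p and q apart.

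The run without the TSC_CTB library whose label reads differentiated, and the runs on index subsets, could not be done, since columns could not be tied to single samples. Depth limits low genes most in the hESC run, where hESC_BAPD3 has 8.57 to 8.74 reads in units of 1e6 and 3 reads amount to 0.343 to 0.350 CPM.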

Other observations

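No gene of cholesterol synthesis and uptake was called higher in TSC_EVT or BAP_40 than in TSC_CTB. From TSC_CTB to TSC_EVT (n = 6 and 6), 0 of 19 rose, 10 fell and 9 did not pass (0 and 10 adjusted over the list alone; adjusted p = 0.00173 by camera, or adjusted p = 0.273 with an estimated correlation). The sterol sensor gene INSIG1 fell from 1202 ± 114 to 366 ± 41.3 CPM (log2 fold change -1.71) and DHCR7 from 563 ± 24.96 to 230.0 ± 16.4 CPM (-1.29). In BAP_40 against TSC_CTB (n = 6 and 6), 0 were higher, 8 lower and 11 did not pass (adjusted p = 2.58e-05, or adjusted p = 0.177 with an estimated correlation). The desaturase gene SCD was at 218 ± 77.1 against 2730 ± 143 CPM (-3.71), and INSIG1 at 69.7 ± 5.41 against 1202 ± 114 CPM (-4.09). Of 20 placental transport genes in the same comparison, 1 was higher, 11 lower and 8 did not pass (adjusted p = 0.000756, or adjusted p = 0.289 with an estimated correlation). The folate receptor gene FOLR1 was at 15.8 ± 6.25 against 208 ± 29.8 CPM (-3.71), and the glucose transporter gene SLC2A1 at 195 ± 36.2 against 789 ± 219 CPM (-1.99).

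Some EVT markers also rose from TSC_CTB to TSC_STB, where 13 of 23 rose, 3 fell and 7 did not pass (n = 6 and 6; adjusted p = 2.78e-07, or adjusted p = 0.0218 with an estimated correlation). HTRA4 rose from 15.5 ± 13.0 to 682 ± 219 CPM (5.71) and SERPINE1 from 52.2 ± 16.3 to 443 ± 101 CPM (3.09), while ASCL2 fell from 86.6 ± 10.6 to 16.2 ± 8.47 CPM (-2.50). Of 11 steroid synthesis genes, 8 rose, 2 fell and 1 did not pass from hESC_BAPD3 to hESC_BAPD7 (n = 3 and 3; adjusted p = 1.09e-10, or adjusted p = 0.0461 with an estimated correlation). CYP11A1 rose from 9.72 ± 1.66 to 3314 ± 493 CPM (8.27) and the sulfatase gene STS from 36.4 ± 3.21 to 183 ± 10.7 CPM (2.30). After median-of-ratios rescaling 8 rose and 0 fell.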
